A study of Mus musculus with 8 samples.

How the data were processed

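RNA was measured on 8 Affymetrix Mouse Gene 1.0 ST arrays, a single-colour platform that reads transcripts along their whole length. The samples came from primary mammary tumors of FvB mice carrying the MMTV-Neu transgene, which drives the rat homolog of the Erbb2 receptor in mammary epithelium. Per the labels, cells of each tumor were sorted into a tumor-initiating cell (TIC) fraction and a CD24-negative fraction, and RNA was purified with the PicoPure kit. Cells of tumors N222 and N229 were mixed in equal parts before the sort, so 5 tumors gave 4 pairs of arrays. The sample titles name the other tumors N251, N260 and N283, whereas the growth protocol lists N250 and N261 where the titles have N251 and N260, and the titles were followed. The markers that defined the TIC gate are not given in the sources used here.

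The deposited values are log2 intensities made by the authors. Per the submitters' processing notes RMA and Partek were used, with versions, settings and genome build not given in the sources used here. The values ran from 1.76 to 14.6 and the medians of the arrays from 7.03 to 7.18. No 2 arrays were duplicates, the highest correlation between arrays being 0.991. The number of arrays limits the precision of every value.

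Of 35556 rows, 21789 carried exactly 1 gene symbol in the platform annotation, 1621 carried several and 12146 none. Symbols were looked up through the gene identifier in a RefSeq table of assembly GRCm38.p6, used for names only, which matched 21698 rows and renamed 0. A gene was represented by its brightest transcript cluster over all arrays, which mattered for 999 genes and left 19938 genes. The 1 named gene with more than 1 cluster was Acaca.

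Differences are the TIC minus the CD24-negative fraction on the log2 scale, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays without a block or a filter on dim genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all adjusted p-values of single genes are from limma. The fit with the tumor as a replicate block was set as an alternative before the data were examined. Both fractions came from the same tumors per the labels, and the deviations of paired arrays from their group means correlated across genes in each tumor (0.32, 0.44, 0.30 and 0.56 for N251, N260, N283 and the pool of N222 and N229). Blocked values are therefore given where they change the call of a named gene or list or move a count by more than 1.5 times.

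Before the data were examined, 38 gene lists were fixed, of which 15 mark cell types. They were tested with limma's camera at its preset correlation of 0.01, adjusted over all lists, for lists with at least 5 measured members. A list's difference is the mean over its members, with the SD over the 4 tumors. With the correlation estimated for each list, 0 of the 38 lists were called and the lowest adjusted p was 0.16; at the preset correlation 22 were called. The fry test, which asks whether a list's genes move on balance one way, called 11. The 2 lists called the published signature were written from memory of the study's publication, with their members not checked against it. The publication chose its signature on these samples. Both lists are counted among the 22 called at the preset correlation and the 11 called by fry.

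Genes were named by a rule fixed before the data were examined. It took Cd24a, Jag1 and Erbb2, and the 15 genes with the largest rise and the 15 with the largest fall among called genes with the same sign in all 4 tumors, leaving out symbols of the form Gm or LOC plus digits or ending in Rik. It also took, in each list, the 3 called members with the largest difference plus up to 2 of the minority direction, or the member with the smallest p where none was called, and the members of the published signature. Genes outside the rule were chosen after their values were seen. They are Cdk1, Top2a, Kif11, Uhrf1, Mcm6, Mki67, Epcam, Krt8, Krt18, Csf1r, Adgre1, Pecam1, Dcn and Slc16a3.

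The fits were tested on simulated data, in 20 draws with 200 of 19938 genes changed, with tumor and residual spreads estimated from the data. Without the block, log2 changes of 1 and 2 were called for 74.2% and 95.3% of the changed genes, and 2.18% of calls were false. With the block the values were 73.0%, 93.6% and 4.62%. With moderated spreads the share of false calls was 1.41% without the block and 6.63% with it. The simulated genes were independent of each other, which real list members are not. Each had the same spread in both fractions, whereas 65.3% of real genes had the larger SD in the CD24-negative fraction. The rates may not carry over to genes of unequal spread. A list shifted by 0.5 was called in 20 of 20 draws, and 2 of 720 tests of lists without a shift were called.

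Alternatives covered the tumor as a fixed or random block, filters on dim genes, the eBayes prior, array weights, 3 further scalings, the mean of a gene's clusters, all rows, stricter thresholds, other list tests, and leaving out each array and each tumor.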

Results

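The series compared 2 sorted fractions of MMTV-Neu mammary tumors, 4 arrays of the TIC fraction and 4 of the CD24-negative fraction, each pair from the same tumor or pool. The comparison asks which transcripts set tumor-initiating cells apart from the CD24-negative cells of the same tumors. The TIC arrays resembled each other more (correlations of 0.979 to 0.991) than the CD24-negative arrays did (0.949 to 0.983). The median SD between arrays of a gene was 0.15 in the TIC fraction and 0.20 in the CD24-negative fraction, and 65.3% of genes had the larger SD in the latter.

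Transcripts of immune cells were far lower in the TIC fraction. Of 19938 genes, 148 fell and 10 rose in the TIC fraction without the tumor as a block (limma), and 98 of those that fell did so by more than 8-fold. Ms4a6c, a membrane protein of myeloid cells, was 75.4-fold lower on average (log2 difference -6.24 ± 0.36 SE, adjusted p = 0.000202). It was lower in all 4 tumors, from -7.33 in N251 to -4.61 in the pool of N222 and N229. With the tumor as a replicate block, 218 genes fell and 172 rose, of which 137 and 9 were also called without the block, and with the tumor as a random block 606 fell and 430 rose. Folds of genes that fell are mean estimates, which background could have made too small, since it was not measured. Many of these genes were dim in the TIC fraction (Ms4a6c at 5.61, where the lower quartiles of the TIC arrays were 5.82 to 5.87). Leaving out both arrays of tumor N260 left 8 lower and 0 higher genes, whereas 1600 genes were higher and 1244 lower at an unadjusted p under 0.05 with all arrays.

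**Figure D1:**
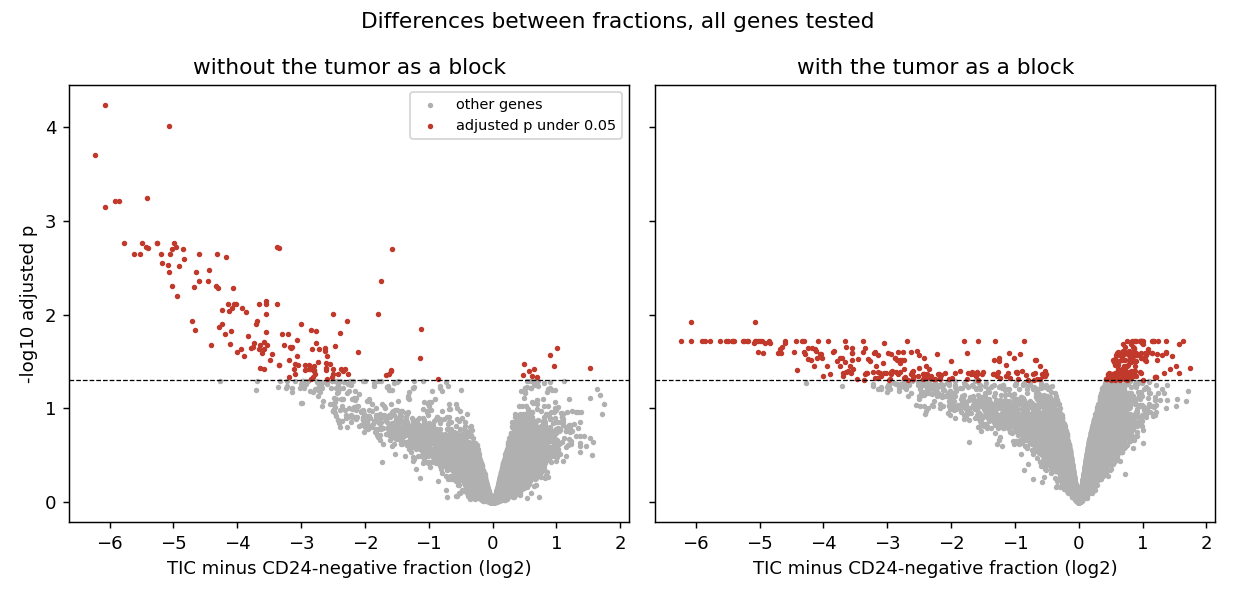
Log2 difference between the TIC and CD24-negative fractions (horizontal) against -log10 of the adjusted p (vertical) for each of 19938 genes, without (left) and with (right) the tumor as a block, with genes under an adjusted p of 0.05 in red. Without the block 148 genes were called lower and 10 higher, and with it 218 and 172.

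Cd24a, Jag1 and Erbb2 were set to be reported whatever their values, Cd24a and Jag1 as presumed sort markers and Erbb2 as the receptor of the transgene. Whether the gate used Jag1 is not given in the sources used here. Its difference therefore cannot be taken as independent of the sort. Cd24a, which encodes the surface protein named in the sort, was at 12.32 ± 0.21 (SD, n = 4) in the TIC fraction and 11.22 ± 0.67 in the CD24-negative fraction. Its RNA was bright in every array of the fraction labelled CD24-negative, from 10.53 in N251 to 12.12 in N283, where the TIC array had 12.50. The log2 difference of 1.11 ± 0.29 (SE) was positive in all 4 tumors and was not called (adjusted p = 0.148, and 0.0691 with the tumor as a fixed block). With the tumor as a random block Cd24a was called (adjusted p = 0.0293). Jag1, a ligand of Notch receptors, differed by -0.91 ± 0.29 and was lower in all 4 tumors (adjusted p = 0.211, 0.0896 with the fixed block and 0.0477 with the random block). Erbb2 differed by 0.44 ± 0.23 (adjusted p = 0.435) and was bright in both fractions, at 12.37 and 11.93. Its difference was 0.97 in N251 and 0.65 in the pool but 0.07 in N260 and 0.05 in N283, and 0.26 without tumor N251.

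Macrophage transcripts fell in all 4 tumors. Of 23 measured macrophage markers 16 fell and 0 rose (22 fell adjusted over the list alone), with a mean difference of -3.60 ± 1.00 (SD over 4 tumors). Lyz2, the lysozyme of myeloid cells, was at 6.33 ± 0.44 in the TIC fraction and 12.10 ± 1.12 in the CD24-negative fraction. It was 54.6-fold lower on average. C1qb, a chain of complement C1q, was 42.8-fold lower on average (adjusted p = 0.000572). Mpeg1, a pore-forming protein of macrophages, was 43.0-fold lower on average (adjusted p = 0.00191). Csf1r, the receptor of the macrophage growth factor, differed by -5.06 and Adgre1, a surface antigen of mature macrophages, by -4.84 (adjusted p = 0.00225 and 0.00255). The list had a camera adjusted p = 2.41e-41, and an adjusted p = 0.16 with an estimated correlation.

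Other leukocyte groups were lower as well. Of 15 pan-leukocyte genes 8 fell (14 adjusted over the list alone), with a mean of -3.24 ± 1.11. They included Cd53, a tetraspanin of leukocytes (-5.50), Laptm5, a lysosomal protein of blood cells (-5.26), and Ptprc, which encodes the CD45 antigen (-4.29, adjusted p = 0.0135). Of 20 T and NK cell genes 3 fell (15 adjusted over the list alone), namely Cd3g of the T cell receptor complex (-5.62) and the granzymes Gzmb (-4.94) and Gzma (-1.80). Of 13 dendritic cell genes 2 fell (8 adjusted over the list alone), Siglech (-1.59) and Cd209a (-1.13). The camera adjusted p-values were 9.25e-26, 8.47e-20 and 3.38e-09 for the pan-leukocyte, T and NK cell and dendritic cell lists, and each list had an adjusted p = 0.16 with an estimated correlation. Of the neutrophil and B cell lists 0 members were called (7 of 13 and 3 of 15 fell adjusted over the list alone, and 1 and 2 with the block). Their means were -0.78 ± 0.44 and -0.48 ± 0.21, with camera adjusted p-values of 2.35e-08 and 8.01e-05. With an estimated correlation these became adjusted p = 0.231 and adjusted p = 0.277.

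Genes of antigen presentation, complement and chemokine signalling followed. Of the complement and Fc receptor genes 5 of 16, and of the MHC class II genes 3 of 13, stand in other lists too. C1qb and Ctss, for example, are also macrophage markers, so these lists are not separate evidence. Of 13 genes of MHC class II presentation 7 fell (12 adjusted over the list alone), with a mean of -2.51 ± 0.66. Among them were Cd74, the invariant chain (-6.08 ± 0.27 SE, 67.5-fold on average, adjusted p = 5.82e-05), H2-Aa (-5.07) and the protease gene Ctss (-5.18). Of 16 complement and Fc receptor genes 9 fell (11 adjusted over the list alone; mean -2.44 ± 0.65), among them the anaphylatoxin receptor gene C3ar1 (-6.07), C1qb (-5.42) and C1qc (-5.03). Of 22 chemokine genes 3 fell (10 adjusted over the list alone and 5 with the block; mean -0.96 ± 0.37), Ccl3 (-5.39), Ccl5 (-3.11) and Ccl2 (-1.62). The 3 lists had camera adjusted p-values of 9.23e-23, 7.06e-16 and 1.06e-10, and each an adjusted p = 0.16 with an estimated correlation. Of 11 measured genes of MHC class I presentation 0 were called, with a mean of -0.02 ± 0.19 (camera adjusted p = 0.525).

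**Figure D2:**
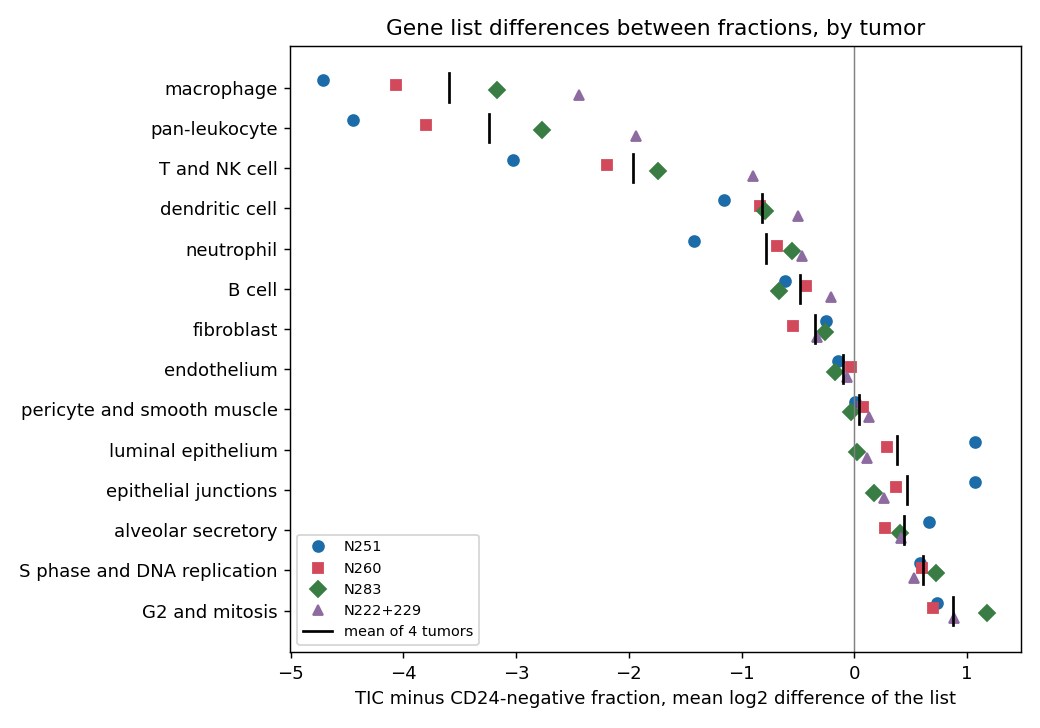
Mean log2 difference (TIC minus CD24-negative fraction) of 14 gene lists in each of the 4 tumors or pools (coloured symbols), with the mean over tumors as a black bar. The macrophage list ran from -4.71 in N251 to -2.44 in the N222 and N229 pool, and the G2 and mitosis list from 0.70 in N260 to 1.18 in N283.

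Markers of stromal cells moved less. Fibroblast markers had a mean of -0.35 ± 0.14 with 0 of 19 called (camera adjusted p = 1.17e-05, and adjusted p = 0.16 with an estimated correlation), of which 6 fell and 1 rose adjusted over the list alone and 1 fell with the block. Serpinf1 differed by -0.70 (adjusted p = 0.0573, and 0.0129 with a random block) and Dcn, a matrix proteoglycan gene, by -1.55 (adjusted p = 0.163). The endothelial list (-0.10 ± 0.07) and the list of pericytes and smooth muscle (0.05 ± 0.07) were not called (camera adjusted p = 0.0960 and 0.978), although the endothelial list was called in 3 settings (without the TIC array of N251, the CD24-negative array of the pool, or tumor N251). Pecam1 of the endothelium differed by -0.64 (adjusted p = 0.276), and by -0.36 without tumor N251. It does not stand for its list: of 20 endothelial genes 4 were higher and 6 lower in all 4 tumors, with a median difference of -0.02. Of 20 genes of the EMT and mesenchymal list 3 fell (8 fell and 1 rose adjusted over the list alone), Tgfbi (-3.38), Zeb2 (-3.06) and Fn1 (-1.58), with a mean of -0.74 ± 0.31 and a camera adjusted p = 1.19e-05. The list had an adjusted p = 0.225 with an estimated correlation. Leukocytes are known to express Zeb2 and Tgfbi too.

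Epithelial transcripts were abundant in both fractions. Epcam stood at 12.09 ± 0.08 in the TIC fraction and 11.69 ± 0.42 in the CD24-negative fraction, Krt8 at 12.73 and 12.30, and Krt18 at 12.22 and 12.07, none of them called. Without tumor N251 the Krt18 difference turned from 0.15 to -0.053. The Epcam difference went from 0.40 to 0.16 and that of Krt8 from 0.43 to 0.14. The luminal list had a mean of 0.38 ± 0.48, with 0 of 22 members called, also adjusted over the list alone. It ranged from 0.03 in N283 to 1.07 in N251, with a mean of 0.145 without N251 (camera adjusted p = 0.000299, and adjusted p = 0.486 with an estimated correlation). The epithelial junction list had a mean of 0.47 ± 0.41 (1.07 in N251, and a mean of 0.27 without it) with 0 of 25 called (1 adjusted over the list alone and 1 with the block), and Cdh3, which encodes P-cadherin, differed by 0.97 (adjusted p = 0.0639, and 0.0424 with the block). Its camera adjusted p = 2.91e-07 became adjusted p = 0.349 with an estimated correlation. The alveolar list, genes of milk production, had a mean of 0.44 ± 0.17, with 0 of 16 called (0 adjusted over the list alone, 2 with the block), and the casein gene Csn2 differed by 0.81 (adjusted p = 0.238, and 0.0286 with the block). Its camera adjusted p = 0.000497 became adjusted p = 0.292 with an estimated correlation.

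Cell-cycle transcripts were higher in the TIC fraction of every tumor, and single members of the 2 cell-cycle lists were not called without the block. The G2 and mitosis list had a mean of 0.88 ± 0.22, and all 29 measured members were higher in all 4 tumors. Without the block 0 of the 29 were called (20 adjusted over the list alone), and with the block 22 rose. The mitotic kinase gene Cdk1 differed by 1.37 ± 0.46 SE (adjusted p = 0.232, and 0.0189 with the block). The kinesin gene Kif11 differed by 1.37, Top2a, a topoisomerase of dividing cells, by 1.21, Mki67 by 0.72 and the checkpoint kinase gene Ttk by 0.97, with blocked adjusted p-values of 0.0255, 0.0459, 0.0424 and 0.0253. With a random block Mki67 was not called (adjusted p = 0.0838). The list of S phase and DNA replication had a mean of 0.61 ± 0.08, with 0 of 29 called (8 adjusted over the list alone) and 14 with the block. Its members Mcm6, a subunit of the replicative helicase, and Uhrf1, which maintains DNA methylation, differed by 0.89 and 0.95 (blocked adjusted p = 0.0189 for both, and 0.0559 and 0.0419 with a random block). The camera adjusted p-values of the G2 and S phase lists were 7.63e-12 and 2.17e-10, and these became adjusted p = 0.367 and adjusted p = 0.349 with an estimated correlation. With an estimated correlation and the block, camera gave an adjusted p = 0.246 for both lists. The fry test gave adjusted p-values of 0.139 and 0.119 without the block, and of 0.0332 and 0.0138 with it.

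The 10 genes that rose without the block changed modestly. Vsnl1, a neuronal calcium sensor gene, was 2.89-fold higher (1.53 ± 0.26 SE, adjusted p = 0.0368, and 0.0798 with the block). Atp1b1, a subunit of the sodium pump, was 2.02-fold higher (adjusted p = 0.0226). Rad18 and Fancb, which act in the repair of damaged DNA, rose by 0.97 and 0.70, and Cnmd, which encodes chondromodulin, by 0.89. Sgms1 of sphingomyelin synthesis rose by 0.62, and AF366264, Mir15b, Glt8d2 and Pih1d2 by 0.65, 0.58, 0.49 and 0.47. Each was higher in all 4 tumors, and 0 of the 10 held at an adjusted p under 0.01.

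**Figure D3:**
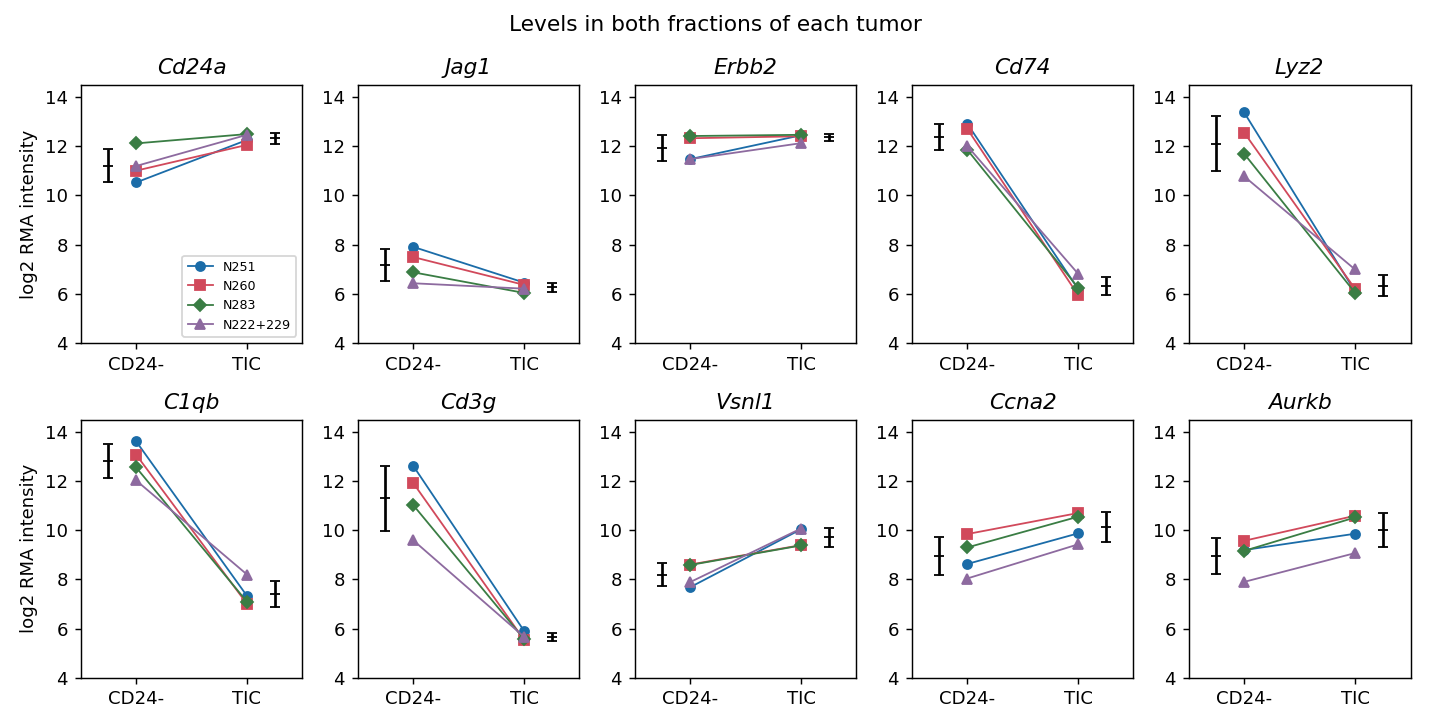
Log2 intensity (vertical axis) of 10 genes in the CD24-negative and TIC fraction of each tumor or pool (lines join a pair), with the mean and SD of 4 arrays beside them. Cd74 averaged 12.38 in the CD24-negative fraction and 6.31 in the TIC fraction, while Ccna2 averaged 8.95 and 10.13.

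A further pair of lists was written from memory of the study's published signature, and their members were not checked against it. That signature was chosen on these samples, so they are not independent evidence of direction. Of 7 measured genes of the remembered upper list 0 were called, all 7 rose adjusted over the list alone, and 6 rose with the block. The mean was 1.26 ± 0.33, with Npy, a neuropeptide gene, at 1.56, Scrn1 at 1.43, Atp7b at 1.34, Cldn8 at 1.27, Ccna2 at 1.18, Aurkb at 1.05 and Chaf1b at 1.01. Of 9 genes of the remembered lower list 5 fell, namely Cd74, C1qb, Cd180 (-4.31), Vcam1 (-3.75) and Nrp1 (-3.34). All 9 fell adjusted over the list alone and 8 with the block. Both lists had an adjusted p = 0.16 with an estimated correlation (camera adjusted p = 1.82e-05 and 2.82e-20).

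The tumors resembled each other in their differences to varying degrees. Across genes, which are not independent replicates, the difference of N251 correlated at 0.882 with that of N260 and at 0.654 with that of the N222 and N229 pool, with the other 4 pairs between 0.706 and 0.821. The SD of the differences over genes was 0.82 in N251, 0.57 in N260, 0.43 in N283 and 0.37 in the N222 and N229 pool. The sign was the same in all 4 tumors for 4626 genes that were higher and 2349 that were lower, 35% of genes where chance gives 12.5%.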

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

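Single arrays far from the other 3 of their group were found in 11 of 268 groups of values, where chance alone gives about 13. In the TIC fraction the pan-leukocyte mean of N251 was 6.585 (others 6.274 to 6.313) and the Wnt pathway mean of N251 was 7.808 (others 7.689 to 7.704). The macrophage gene Lyz2 was at 6.989 in the N222 and N229 pool (others 6.043 to 6.201), Ccl3 at 6.317 in N251, and Ccl2 at 6.561 in N260. The Wnt antagonist gene Sfrp1 was at 10.41 in the N222 and N229 pool (others 9.687 to 9.792), Pfkfb3 at 6.042 in N283, and Krt8 at 13.08 in the N222 and N229 pool. In the CD24-negative fraction the collagen and matrix mean of the N222 and N229 pool was 7.213 (others 7.406 to 7.441), the Wnt pathway mean of N283 was 7.78, and Ccl2 was at 9.343 in N251. Among rows without exactly 1 gene symbol, which the comparison did not use, 12 fell in the TIC fraction and 1 rose when all rows were tested.

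The CD24-negative array of tumor N251 stood apart, with a mean deviation of 0.272 from its group against 0.128 to 0.242 for the others. A higher leukocyte share in that array is a candidate explanation: its deviation from the CD24-negative arrays of N283 and the N222 and N229 pool followed, across genes, the difference between fractions of N260, with a correlation of 0.685. That profile takes in all genes that set the N260 fractions apart, not leukocyte genes alone. A defect of the array as a whole stays open. After that profile was removed its residual spread was 1.29 times the mean of those of N283 and the N222 and N229 pool, between the bounds of 1.2 and 1.5 set beforehand. The residual spreads were 0.453 in N251, 0.273 in N283 and 0.428 in the pool. The deviations of N283 and the pool were taken from means that include the N251 array. A defect of that array would raise their spreads too and pull the ratio down.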

How the results depend on the processing

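The blocked fit without N251, camera with an estimated correlation and fry each combined with the block, and settings for agreement between tumors were chosen after seeing the data. Against 10 higher and 148 lower genes, the higher count was 172 with the tumor as a replicate block, 5 for genes at or above the median level, 19 after median centring, 6 after cyclic loess, and 2 both with all rows and at 2-fold or more. At an adjusted p under 0.01 it was 0, with 58 lower. Higher and lower counts were 430 and 606 with the tumor as a random block, 191 and 778 with array weights, and 360 and 480 with the replicate block and no N251 arrays. Leaving out an array or a tumor gave 0 to 46 higher genes (46 without CD24-negative N283) and 8 to 583 lower genes (8 without tumor N260, 583 without the CD24-negative array of the pool). Each array and tumor moved the higher count by more than 1.5 times, and all moved the lower count so except CD24-negative N283 (160) and tumor N251 (118). The other lower counts were 52, 58, 55 and 53 without the TIC array of N251, N260, N283 and the pool, 314 and 56 without the CD24-negative array of N251 and N260, and 42 and 225 without tumor N283 and the pool. Of the 158 calls, 105 were shared without tumor N251, 7 without N260, 42 without N283 and 138 without the pool; the cause was not tested, though fewer arrays enter each fit. Against 8 higher and 14 lower lists, an estimated correlation called 0 higher and 0 lower, and 0 and 0 together with a replicate block, where it allows for members that vary together. The fry test called 1 higher list, the remembered upper signature, which was chosen on these samples. It called 10 lower lists, the remembered lower signature among them. With a replicate block fry called 4 higher (alveolar, S phase, and G2 and mitosis gained) and 9 lower (T and NK cell lost, adjusted p = 0.0603). With camera at its preset correlation the replicate block changed no list call (8 and 14). Mean agreement between tumors was 0.758, and 0.56 with all rows, the cause of which was not tested. Krt18 ran from -0.053 without tumor N251 to 0.25 without N283. Of 43 named genes that were called, 28 held in every setting that kept all arrays, and 36 lost the call in at least 1 setting. Other scalings moved the median difference of all genes from 0.04 to at most 0.09. Signal over background was not measured here, so dim genes such as Mir15b (4.67 and 4.10) have an unknown margin.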

Other observations

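Some tests here, those of tumor cell dilution, of stromal cells and of the order of tumors, were chosen only after the results were seen. Among gene groups not described above, cholesterol and fatty acid synthesis had a mean of 0.33 ± 0.20 (camera adjusted p = 0.000433, and adjusted p = 0.469 with an estimated correlation), with Acaca, the enzyme that commits carbon to fatty acids, at 0.65. Mitochondrial respiration had a mean of 0.21 ± 0.21 (adjusted p = 0.000863, and adjusted p = 0.501 with an estimated correlation) and lost its call without the CD24-negative array of N251 (mean of 0.11 without that tumor). The immediate-early and heat shock list had a mean of -0.45 ± 0.43 (adjusted p = 0.000299, and adjusted p = 0.381 with an estimated correlation), from -1.03 in N251 to -0.02 in the N222 and N229 pool and a mean of -0.25 without N251, with Dusp1 at -2.00. The interferon list had a mean of -0.31 ± 0.33 (adjusted p = 0.0122, and adjusted p = 0.522 with an estimated correlation), with Cxcl9 at -1.66 and a mean of -0.17 without N251, and lost its call without tumor N251, without tumor N260, and without the TIC array of N251, the CD24-negative array of N260 or the TIC array of the pool. Of these 4 lists 0 members were called, and adjusted over the list alone 2 interferon genes fell. With the block 1 gene of the cholesterol list rose. With a random block Acaca, Dusp1 and Cxcl9 were called (adjusted p = 0.0403, 0.03 and 0.0169).

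The other 13 lists were not called, although ErbB receptors and ligands were called in 9 of 29 alternative settings (both filters on dim genes, cyclic loess, all rows, ranks and 4 that leave out arrays), mammary stem markers in 2, and the collagen, Notch, TGF-beta and p53 lists in 1 each. Abcg2 of the mammary stem list differed by 0.98 (adjusted p = 0.126, and 0.0265 with a random block). The mean was 0.22 for mammary stem and progenitor markers (0.11 without tumor N251). It was 0.24 for ErbB receptors and ligands (0.087 without tumor N251). Means were 0.12 for basal and myoepithelium, 0.29 for erythroid genes, 0.08 for the Wnt pathway and 0.07 for hypoxia. They were -0.10 for the Notch pathway, -0.11 for both TGF-beta with BMP signalling and p53 targets, -0.21 for adipocytes and -0.06 for mast cells. Collagen and matrix genes had a mean of 0.01 and a median of -0.10, glycolysis a mean of -0.0045 and a median of 0.08, and the TGF-beta list a median of 0.01, so that mean and median differed in sign. The means of the Wnt, hypoxia, mast cell, collagen and glycolysis lists, all within 0.08 of 0, moved by more than 1.5 times or changed sign without at least 1 tumor. With the block Oxtr (1.21) of the basal list and Car2 (0.86) of the erythroid list rose, and Lpl (-2.22) of the adipocyte list, Col14a1 (-1.09) of the matrix list, and Pfkfb3 (-1.52) and Slc16a3 (-0.61) of glycolysis fell. Slc16a3 was chosen after its values were seen.

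Chance as the source of the gene calls was tested over all 35 splits of the 8 arrays into 4 and 4: only the real split gave as many as 158 genes, a count of 1, and the highest other gave 0. With the block, 8 splits part all 4 pairs, too few for a share under 0.05, and the real one gave 390 genes against a highest other of 0, again a count of 1. For gene lists 5 of the 35 splits gave 22 lists or more, the highest other 25, so chance could not be excluded for the number of lists called. The other splits that reached 22 each kept most of the CD24-negative arrays on the same side. They therefore carried part of the real contrast, and the count of lists cannot separate chance from it. Among the 8 splits that part all pairs, 2 others also gave 22.

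For the lower leukocyte transcripts, leukocytes in the CD24-negative fraction in tumor-specific amounts are a hypothesis that stays open. The transcripts were bright there (C1qb 12.82, Cd74 12.38), 7 of the 23 macrophage markers stand in other lists too, and any gate against leukocytes is not given in the sources used here. The macrophage, T and NK cell, neutrophil, dendritic cell and pan-leukocyte lists, 5 in number, ranked the tumors N251, N260, N283 and the pool. The B cell list put N283 first. Of 27 lists without a leukocyte theme 5 also had that order, among them interferon response and EMT. Leukocytes are known to express Zeb2 and Tgfbi of the EMT list, so the 27 are no leukocyte-free comparison. The shared order therefore cannot decide whether leukocytes are the source. The MHC class II, complement, chemokine and lower signature lists had that order too. They were not among the 27, and neither were the B and mast cell lists. Fewer tumor cells in that fraction, with every other cell type up alike, also stays open: the pan-leukocyte difference exceeded the largest stromal one by a mean of 2.89 ± 1.10 (SD), but the 3 stromal lists were dim in both fractions (6.41 to 6.996, with the lowest array median at 7.03), which excludes nothing. The leukocyte lists were as dim in the TIC fraction (macrophage 6.38) and did rise in the other, and the collagen and matrix list, at 7.38 and 7.37, differed by 0.01 ± 0.06, but how much of its signal came from tumor cells was not measured.

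For the higher cell-cycle transcripts, fewer tumor cells in the CD24-negative fraction were taken to lower epithelial junction genes as much as cell-cycle genes. This holds only if the other cells there express neither set and if genes of unlike brightness respond alike, which was not checked. The excess of the G2 and mitosis list over the junction list was -0.331 in N251, 0.33 in N260, 1.01 in N283 and 0.62 in the pool, a mean of 0.406 ± 0.564 (SD), so the tumors did not decide it. Under 3 further scalings the lowest of 12 differences was 0.63. A shift common to all genes that scaling had left in the values would move the median gene as much as the list. The median difference of all genes was 0.04 as deposited and at most 0.09 under the other scalings. By tumor the median was at most 0.08, against 0.70 or more for the G2 and mitosis list. These values argue only against a shift left in the deposited values. Scaling brings array medians together, so a shift that the scaling itself gave all genes cannot be seen in the median. Such a shift stays open. None of the scalings moved that median far, so a scaling error limited to some genes stays open too. A larger share of cycling cells in the TIC fraction is a hypothesis that was not tested.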
